A study of Glycine max with 7 samples.

How the data were processed

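The 7 samples are nodules of soybean (Glycine max) roots that had been transformed with Agrobacterium rhizogenes, which produces transgenic hairy roots on an untransformed shoot. Per the labels' protocols, 4 samples carried a hairpin made from 359 bp of the 3′ UTR of GmbHLHm1, a basic helix-loop-helix transcription factor, and 3 samples carried the empty vector. Nodules had been induced with Bradyrhizobium japonicum USDA110 and were sampled 24 days after inoculation. RNA was taken from individual plants' nodules, and 250 ng per array was labelled with biotin. The labels speak of 4 biological replicates, and 3 vector arrays are analysed here. The labels also state that samples with similar GmbHLHm1 RNA levels by qPCR were picked for the arrays, so the spread within a group describes picked plants.

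Each array has 66555 probe sets. The authors deposited 1 value per probe set and array, and the submitters' processing notes name Partek and RMA without a version or a role for either. RMA subtracts background, quantile normalizes probes between arrays and summarises each probe set, and the authors' deposited values have the range of a log2 scale, which no header states. The genome build, the annotation, the probe filters and the statistical test are not given in the sources used here. The values were used as deposited, without centring and without a filter on dim probe sets. Control probe sets were not separated from the others, because no list of them was used here. Array medians lay between 0.596 and 0.623 log2 units and the highest values between 12.7 and 12.9. Between 75.9% and 78.3% of the values of an array were below 1 log2 unit, where RMA values crowd at a floor and differences are compressed. Only 6620 probe sets had a mean of at least 2 log2 units, and these are called brighter here. Arrays have no read depth, so the precision is limited by their number.

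Gene names came from the platform annotation, with symbols updated by gene ID through a table of the Glycine_max_v4.0 assembly. This annotation listed 3139 probe sets, of which 3085 had 1 gene and 54 had several, while 63416 probe sets had no gene listed and are unnamed here. The 3085 probe sets stand for 2952 genes, and 718 of these genes (779 probe sets) have a symbol other than a LOC number. A gene with several probe sets was represented by the one with the highest mean over the 7 arrays. No coordinates are given, because the build behind the array is not stated.

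RNAi was compared with vector by limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes on the 7 arrays, no covariate and Benjamini-Hochberg adjustment over all 66555 probe sets. The threshold was an adjusted p of 0.05, and every limma p is two-sided. Gene lists were tested with camera at a preset correlation of 0.01 over the 2952 genes, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Correlations and single values were tested by exact permutation in SciPy 1.17.1. With 4 and 3 arrays there are 35 splits, and the two-sided exact test of a group difference used here, which doubles the smaller tail, cannot give a p below 0.0571.

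The design, most alternatives and 29 gene lists defined by words in gene descriptions were fixed before the data were examined. The filters at a mean of 2 log2 units and at the upper quartile and upper decile of the mean, and the trend prior without robust fitting, were added afterwards. The tables used here give symbols without descriptions, so none of the 29 lists reached the minimum of 3 members. They had at most 2, and 24 of them had 0. They were replaced by 27 lists of symbols, written after the probe names had been read and before any comparison of the groups. The lists planned as markers of infected cells, attached root, vascular tissue and dividing cells were therefore not tested, and a photosynthesis list stands for green tissue. The target was to be found by its name, by SAT1 or by its locus. The rule met 1 probe set, with the symbol SAT1, whose gene ID belongs to another gene than the one that the reference table lists with SAT1 as a synonym.

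The genes named were chosen by a rule: the genes past the threshold, and up to 4 members by smallest p from each list described. The first part was filled to 5 in each direction by the smallest p. Only genes with a symbol whose RNAi arrays all lay above or all below the vector arrays could fill it. Which 13 lists are described, and with how many members, was chosen after the list results and the members' values had been seen. The senescence and GASA lists were included because VPE and GASA22 stood out. Genes outside the rule are marked where they appear.

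The procedure was tested on simulated arrays with the means and spreads of these probe sets. In 100 brighter probe sets changed by 1 log2 unit 26% were recovered, and in 100 changed by 2 log2 units 71% were recovered, with 6 false calls among 66555 probe sets. Both sets were changed in the same simulated arrays, and all probe sets varied independently. The shares are therefore not the power of the real comparison. On the 6620 brighter probe sets alone the shares were 45% and 90%. With no change simulated, 0 probe sets were called. A shift of -0.5 log2 units in the purine and ureide list was recovered at a camera adjusted p of 2.2e-11 with 0 other lists called, in a simulation whose genes varied independently. Alternatives covered the scaling between arrays, the filter on dim probe sets, the prior, array weights, a minimum fold of 2, the replicate number as a block and leaving out each array in turn.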

Results

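Gene expression was measured on 7 arrays of soybean nodules 24 days after inoculation, 4 from plants carrying an RNAi hairpin against GmbHLHm1 and 3 from plants carrying the empty vector. Each sample was RNA from the nodules of a single plant. Over all 66555 probe sets, Pearson's r between arrays was 0.959 to 0.977 within the RNAi group, 0.973 to 0.981 within the vector group and 0.949 to 0.979 between the groups. These correlations are across probe sets, which are not independent replicates.

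The first question was whether the hairpin lowered its target. No probe set carried the name GmbHLHm1, so the knock-down was not checked on these arrays and the groups rest on the labels. The probe set with the symbol SAT1 (12156564), a name also used for GmbHLHm1, belongs to another gene ID in the reference table. Its signal was near the floor, at 0.79 ± 0.15 log2 units (SD, n = 4) in RNAi nodules and 1.04 ± 0.38 (SD, n = 3) in vector nodules. The difference of -0.25 was within the spread between replicates (exact permutation test over 35 splits, two-sided p = 0.40).

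The series was made to find which nodule transcripts differ when GmbHLHm1 expression is lost. Among the 10 genes that the rule named by smallest p, CA1, whose symbol stands for carbonic anhydrase, was on the higher side in RNAi nodules. On the lower side was the uricase gene UR2, which acts in the ureide pathway that exports fixed nitrogen from soybean nodules. CA1 had a signal of 8.48 ± 0.33 log2 units in RNAi nodules (SD, n = 4) and 7.35 ± 0.21 in vector nodules (SD, n = 3), a difference of 1.13 (SE 0.20) or 2.19-fold. UR2 had 6.96 ± 0.32 in RNAi nodules (SD, n = 4) and 7.99 ± 0.41 in vector nodules (SD, n = 3), a difference of -1.03 (SE 0.24), so that its signal was 2.04-fold higher in vector nodules. For both genes the 4 RNAi arrays lay on 1 side of the 3 vector arrays, which the naming rule required. For neither did the difference pass the test (limma, adjusted p = 0.847).

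The vacuolar processing enzyme gene VPE, a cysteine protease of the vacuole, had 1.92 ± 0.50 in RNAi nodules (SD, n = 4) against 3.36 ± 0.63 in vector nodules (SD, n = 3), a difference of -1.44. HDL56 differed by -0.64 (5.34 against 5.98). GAI2, named as a member of the DELLA family of gibberellin signalling repressors, differed by 0.33 (5.93 against 5.60). The other 5 genes named by smallest p were near the floor, at mean signals below 1.5 log2 units. They were SCAM-4 (0.29), STP (0.35) and ATG8d (0.20) on the higher side and AKR1 (-0.32) and GSTU42 (-0.43) on the lower side. All 10 genes had a limma adjusted p of 0.847.

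**Figure D1:**
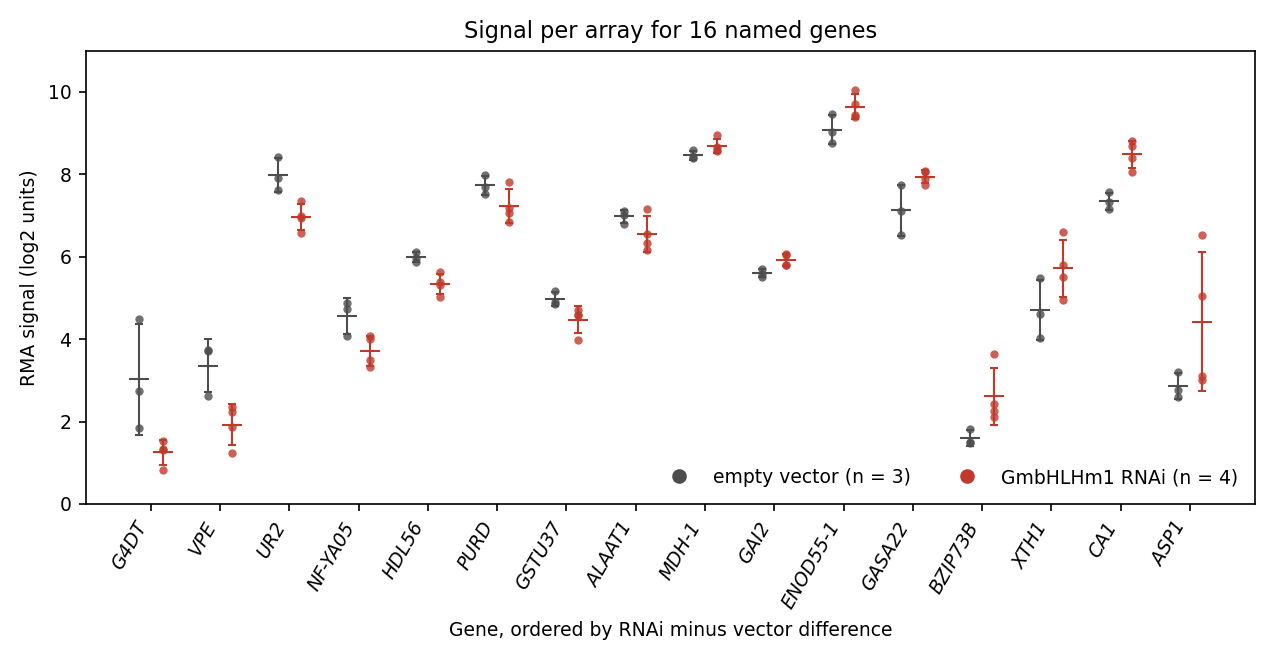
Signal of 16 named genes with a mean of at least 2 log2 units (vertical axis, RMA signal in log2 units), the 8 lowest and the 8 highest by RNAi minus vector difference (horizontal axis). Points are arrays, horizontal marks are group means and bars are the SD (vector n = 3, RNAi n = 4); CA1 lies at 8.48 in RNAi and 7.35 in vector nodules, while the RNAi arrays of ASP1 spread from 3.01 to 6.53.

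Over all 66555 probe sets, limma called 0 higher and 0 lower at an adjusted p of 0.05, and the lowest adjusted p was 0.163. An unadjusted p under 0.05 was reached by 3260 probe sets, 1354 higher and 1906 lower in RNAi nodules, where 3328 would be reached by chance. Among the 6620 brighter probe sets 825 reached it in this fit and 630 when they were fitted alone, where chance gives 331. Probe sets are not independent, so such counts can lie far from the chance values given here without a group difference. A difference of at least 2-fold was seen in 224 probe sets, 110 higher and 114 lower. In 105 of these, 39 higher and 66 lower, the groups did not overlap. The groups did not overlap in 3.96% of all probe sets, in 5.57% of the 33277 with the higher means and in 9.59% (635) of the brighter ones, where chance gives 5.71%. This chance value holds for values without ties, and ties lower it. Between 11.4% and 13.6% of the values of any 2 arrays were identical, and 2.0% to 4.9% among the brighter probe sets. Unnamed probe sets were picked by smallest p among those whose groups did not overlap. They were 12107695 (6.24 ± 0.02, SD, n = 4, in RNAi and 5.43 ± 0.10, SD, n = 3, in vector nodules) and 12021778 (3.38 against 1.71) on the higher side. On the lower side, 11956539 had 1.03 in RNAi and 1.34 in vector nodules. Probe set 12161099, named after its values were seen, had 0.86 ± 0.06 (SD, n = 4) in RNAi and 3.28 ± 0.69 (SD, n = 3) in vector nodules (limma adjusted p = 0.772); it passed the threshold once vector replicate 1 was left out (adjusted p = 0.0251).

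Of the 27 gene lists, 0 passed an adjusted p of 0.05 in camera, and 0 of their 406 genes passed over all probe sets. In 3 lists the unadjusted camera p was under 0.05, all on the lower side: purine and ureide, circadian clock and light, and defence proteins, each with a camera adjusted p of 0.0968. With an estimated correlation, their adjusted p was 0.764, 0.621 and 0.621. Adjusted over the list alone, 2 members passed, UR2 in the purine and ureide list and GSTU42 among the glutathione transferases. UR2 is also in the nodulins list, where it did not pass. This adjustment does not account for looking within 27 lists. These lists were written after the probe names had been read.

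The purine and ureide list follows the route from purine synthesis to ureides. Of its 8 genes, 6 were lower and 2 higher in RNAi nodules, with a median difference of -0.20, and 0 passed the test over all probe sets. Beside UR2, PURD and PUR3, both of purine synthesis, differed by -0.51 (7.22 ± 0.41, SD, n = 4, against 7.73 ± 0.24, SD, n = 3) and -0.33 (7.26 against 7.59). IMPDH1, of guanine nucleotide synthesis, differed by 0.20. UR9, the other uricase gene in the list and named after its values were seen, had 10.10 in both groups. The camera adjusted p of this list was 0.0226 without RNAi replicate 4 and 0.686 without RNAi replicate 1, both at the preset correlation. With an estimated correlation, run on all 7 arrays only, its adjusted p was 0.764.

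The nodulins are genes known for their expression in nodules. Of 15, 14 of them brighter, 9 were higher and 6 lower, with a median of 0.00 (camera adjusted p = 0.882). N-44 was at 10.37 in RNAi and 10.18 in vector nodules (a difference of 0.19, or 0.09 after quantile normalization), ENOD93 at 9.78 and 9.65, and ENOD55-1 at 9.65 ± 0.30 (SD, n = 4) and 9.09 ± 0.35 (SD, n = 3). The nodulation signalling list had 5 genes, 2 higher and 3 lower (median -0.02, adjusted p = 0.492). In it, NF-YA05, a subunit of the nuclear factor Y complex, differed by -0.84 (3.72 ± 0.36, SD, n = 4, against 4.56 ± 0.43, SD, n = 3), and NFR5A, named for a Nod factor receptor, by -0.02 at the floor.

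In nitrogen assimilation and nitrate, 5 genes were higher and 7 lower (median -0.03, camera adjusted p = 0.771). ASP1 differed by 1.57 with an SE of 0.89, since its 4 RNAi arrays read 6.53, 3.11, 3.01 and 5.05, and by 0.86 without RNAi replicate 1. ALAAT1, an alanine aminotransferase, differed by -0.43 (6.55 against 6.98). The glutamate dehydrogenase genes GDH2 and GDH1 differed by 0.20 and -0.15, both near the floor. In carbon supply 8 genes were higher and 6 lower (median 0.13, adjusted p = 0.540). The malate dehydrogenase gene MDH-1 was at 8.69 against 8.46 (0.22, or 0.14 without RNAi replicate 1), and PEPC17 and PEPC16, of phosphoenolpyruvate carboxylase, differed by 0.14 each near the floor.

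The circadian clock and light list had 2 genes higher and 6 lower (median -0.08), and 1 of its 8 genes was brighter. TOC1, a core component of the plant clock, differed by -0.33, the photoreceptor gene PHYA by -0.25, FKF1 by -0.18 and MYB114 by 0.28, all at means below 1.2 log2 units. Without vector replicate 1 PHYA differed by -0.16, without RNAi replicate 1 FKF1 by -0.09 (-0.11 without vector replicate 3) and without RNAi replicate 3 MYB114 by 0.11. In the fry test for change in either direction, which does not compare a list with other genes, this list had an adjusted p of 0.0111. Its adjusted p was 0.765 in the one-directional fry test and 0.621 in camera with an estimated correlation. Of 14 defence proteins 4 were higher and 10 lower (median -0.08), and 2 were brighter. On the 33277 probe sets with the higher means, 7 of them remained, with an unadjusted camera p of 0.274 (adjusted 0.532). There the unadjusted camera p was 0.0135 for purine and ureide and 0.0337 for circadian clock and light (adjusted 0.290 for each). PR-10 differed by -0.25, the osmotin-like gene OLPb by -0.16 and the Bowman-Birk inhibitor gene BBI-1 by -0.20, all at the floor. OLPb differed by -0.11 without vector replicate 1 and BBI-1 by -0.13 without RNAi replicate 1.

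Cell wall genes were higher in 9 and lower in 2 of 11 (median 0.14, camera adjusted p = 0.414). XTH1, of xyloglucan remodelling, was at 5.71 ± 0.69 (SD, n = 4) against 4.71 ± 0.74 (SD, n = 3), a difference of 1.01, or 0.67 without vector replicate 1. The expansin genes CIM1 and EXP1 differed by 1.29 and 0.35, EXP1 by 0.23 without vector replicate 1. Their mean signals were low, at 1.86 and 0.96 log2 units, the latter near the floor. Of 28 phenylpropanoid and isoflavonoid genes 15 were higher and 13 lower (median 0.01, adjusted p = 0.663). G4DT, a prenyltransferase of glyceollin synthesis, was at 1.25 ± 0.30 (SD, n = 4) in RNAi and 3.03 ± 1.34 (SD, n = 3) in vector nodules, a difference of -1.78 with the vector arrays spread from 1.85 to 4.49, or -1.04 without vector replicate 1. The chalcone isomerase gene CHI1A differed by -0.43 and 4CL1 by -0.17, near the floor at mean signals of 1.31 and 0.90 log2 units.

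Glutathione transferases were higher in 8 and lower in 14 of 22 (median -0.04, adjusted p = 0.414), with GSTU37 at -0.51, GSTT1 at -0.39 and GSTU62 at 0.46 beside GSTU42. RNAi replicate 1 read 3.98 for GSTU37, below the 4.59 to 4.70 of the other RNAi arrays. In bZIP transcription factors 3 were higher and 5 lower (median -0.15, adjusted p = 0.587), with BZIP73B at 1.01 and BZIP36 at -0.10. BZIP36 was at the floor, at a mean signal of 0.66 log2 units. RNAi replicate 3 read 3.63 for BZIP73B and the other RNAi arrays 2.11 to 2.43, and the difference was 0.66 without it. The senescence and proteolysis list, which holds VPE, had 4 genes higher and 3 lower (median 0.04, adjusted p = 0.846), with the stay-green gene SGR1 at 0.14, or 0.08 without vector replicate 2. SGR1 was at the floor, at a mean signal of 0.69 log2 units. Of 14 GASA peptides 10 were higher and 4 lower (median 0.03, adjusted p = 0.587), and GASA22 was at 7.95 ± 0.15 (SD, n = 4) in RNAi and 7.13 ± 0.62 (SD, n = 3) in vector nodules, a difference of 0.82, or 0.52 without vector replicate 2.

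The other 14 lists had camera adjusted p-values from 0.414 to 0.887. Higher and lower genes numbered 4 and 0 in aquaporins (median 0.11, adjusted p = 0.511), 11 and 6 in NAC transcription factors (0.10, 0.511), 4 and 2 in photosynthesis (0.02, 0.887) and 4 and 5 in housekeeping (-0.01, 0.887). They numbered 6 and 7 in iron and haem (-0.03, 0.587), 6 and 10 in redox (-0.08, 0.414), 6 and 7 in lipoxygenase and jasmonate (-0.04, 0.690) and 8 and 8 in hormones (0.00, 0.690). In WRKY transcription factors 28 were higher and 28 lower (0.00, 0.846). The counts were 5 and 8 in WNK kinases (-0.03, 0.587), 3 and 6 in heat shock and chaperones (-0.03, 0.771) and 18 and 19 in seed maturation and storage (0.00, 0.492). In fatty acid synthesis and desaturation they were 13 and 12 (0.00, 0.690), and in sulphur and polyamine 7 and 5 (0.01, 0.690). Median, mean and test differed in sign in 8 lists: nodulins, nitrogen assimilation and nitrate, phenylpropanoid and isoflavonoid, WRKY transcription factors, senescence and proteolysis, fatty acid synthesis and desaturation, sulphur and polyamine, and housekeeping.

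**Figure D2:**
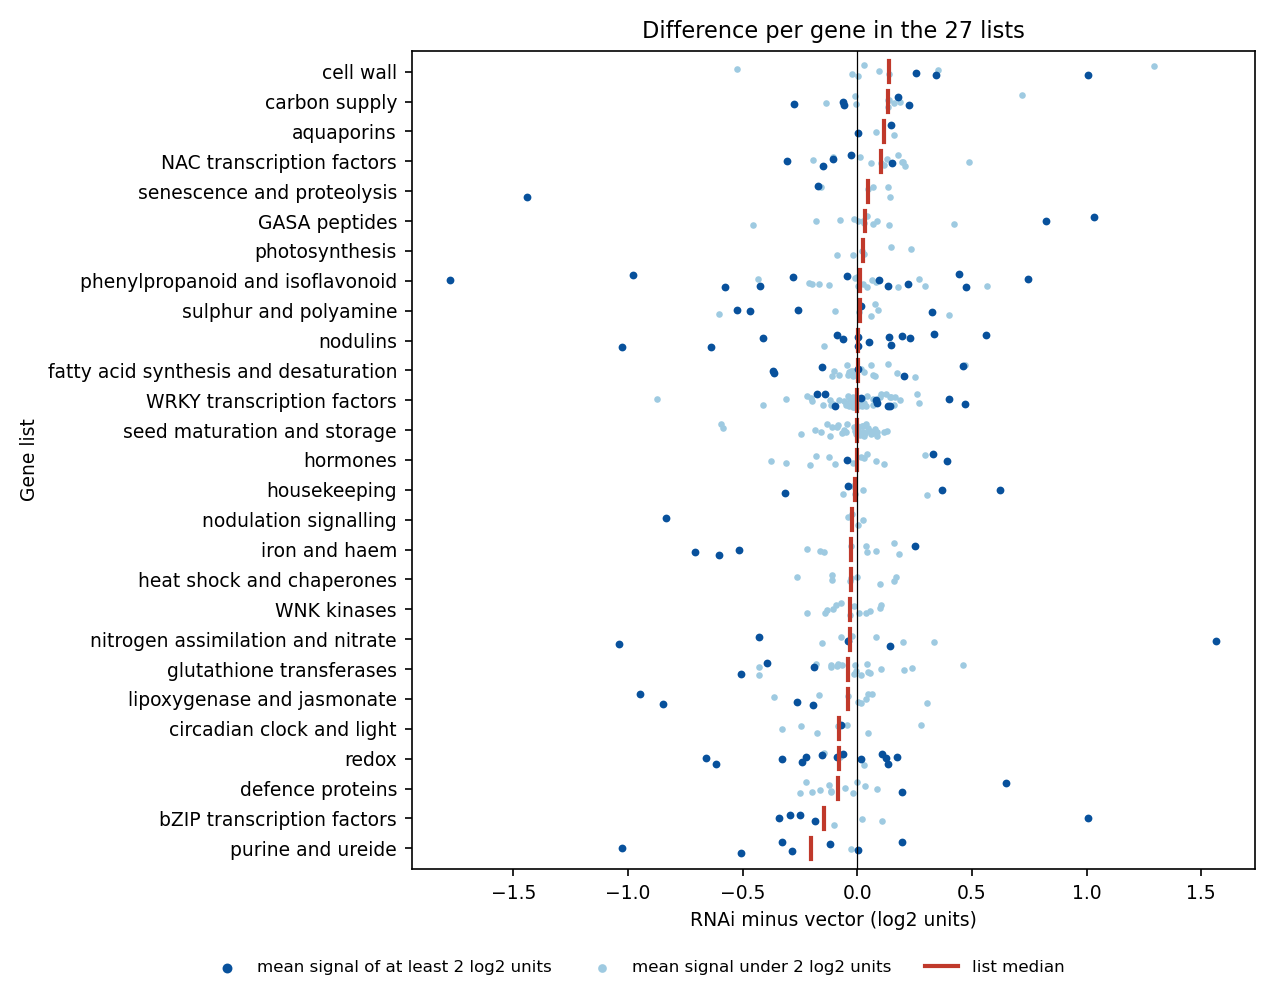
RNAi minus vector difference in log2 units (horizontal axis) of each gene in the 27 lists (vertical axis, ordered by list median). Dark points are genes with a mean of at least 2 log2 units, pale points are dimmer genes and red bars are list medians, which run from -0.20 in purine and ureide to 0.14 in cell wall.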

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

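The 95% interval below was added after its share had been seen; the test itself was set before. Of the 45 named genes, 1 had an RNAi array far from the other 3 arrays of its group. GSTU37 read 3.98 log2 units in RNAi replicate 1, while the other RNAi arrays read 4.59 to 4.70. Chance gives such a gap in about 1 of 20 groups.

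The same gap was counted over the 6620 brighter probe sets, where 672 (10.2%) had 1 RNAi array far from the rest. If RNAi replicate 1 alone were the source, it should be the far array in over 50% of these. It was so in 30.5% (205 probe sets; 95% interval 27.04% to 34.1%), RNAi replicate 2 in 39.7% (267), RNAi replicate 3 in 13.5% (91) and RNAi replicate 4 in 16.2% (109). This argues against replicate 1 as the main source, but the interval reaches past the bound of 33.3% set for excluding it, so a smaller part stays open. Probe sets are not independent, which makes the interval too narrow. No biological explanation was tested, since the labels name no difference among the RNAi plants.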

How the results depend on the processing

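The filter at a mean of 2 log2 units, those at the upper quartile and upper decile of the mean, the trend prior without robust fitting and the symbol lists were chosen after seeing the data. Limma called 0 probe sets higher and 0 lower under every setting run except 1: without vector replicate 1, 1 probe set was lower (12161099; range over leaving out each array 0 to 1). Lists were tested with camera under both scalings, the filters at the median and at 2 log2 units, the block, an estimated correlation and leaving out each array, and with fry on the values as deposited. In camera and the one-directional fry test 0 lists passed under these except 1 with the replicate number as a block and 1 without RNAi replicate 4 (range 0 to 1), in both cases purine and ureide, with adjusted p of 0.0253 and 0.0226 at the preset correlation. With all 7 arrays and an estimated correlation its adjusted p was 0.764, and the estimated correlation was not run for those 2 fits. Its adjusted p ran from 0.0226 to 0.686 over leaving out each array. RNAi replicate 4 has no vector partner, so the block leaves it out too, and both exceptions rest on the same 6 arrays and the same differences (UR2 -1.16 in each). RNAi replicate 4 read the highest of the RNAi arrays for UR2 (7.36), PURD (7.80) and PUR3 (7.54), though not for IMPDH1 (3.09). Leaving it out enlarged the differences of UR2, PURD and PUR3. For 12161099, vector replicate 1 read 4.07 and the other vector arrays 2.97 and 2.80. Without vector replicate 1 its difference was -2.02 (SE 0.06), against -2.42 (SE 0.30) with all arrays. What sets RNAi replicate 4 and vector replicate 1 apart was not tested. Over the 33277 probe sets with the higher means, deviations of same-numbered arrays correlated at -0.05, -0.16 and 0.23. Those of differently numbered arrays correlated at -0.30 to 0.31. The same-numbered arrays did not stand out as a set, but so few pairs cannot exclude that the numbers pair the samples. The block gave 4053 probe sets with unadjusted p under 0.05 against 3595 without RNAi replicate 4 and 3260 with all arrays, and changed no other call. Of 833 values of the 45 named genes under alternatives, 832 kept their direction. Many of them could not reverse, so this count is partly fixed in advance. The filters, the priors and the fit without moderation leave the difference itself unchanged. Genes whose groups did not overlap cannot reverse when 1 array is left out. Leaving out 1 array moved the difference of 14 genes by over 1.5 times. Another setting did so for 2, N-44 (0.09 after quantile normalization) and NFR5A (-0.048 with the block). NFR5A alone reversed, to 0.0018 without RNAi replicate 3 (range -0.072 to 0.0018). The SAT1 probe set stayed lower (range -0.37 to -0.03) and did not pass. Scaling moved the median of all probe sets by less than 0.01. The planned lists by description could not be tested, and no alternative was run for GmbHLHm1 itself. Values below 1 log2 unit, at least 75.9% of each array, lie near the floor and limit what the arrays can show.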

Other observations

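The tests of a single array, of nodule content, of the count of called probe sets and of the AS1 and ASP1 relation below were chosen after the result was seen, and so were the intervals and the use of left-out arrays as the spread of the normalization test. Genes in this paragraph were chosen after their values were seen. The haem oxygenase genes HO1 and HO3, whose product opens the haem ring, and the lipoxygenase gene LOX9 had a larger SD among the vector arrays than the difference between groups. HO1 read 6.61, 4.70 and 6.21 log2 units in the 3 vector arrays and 4.47 to 5.54 in the RNAi arrays. HO3 ranged from 4.95 to 6.22 in the vector arrays and from 4.46 to 5.53 in the RNAi arrays. LOX9 read 6.16, 3.92 and 6.51 in the vector arrays and 3.46, 5.05, 5.99 and 3.82 in the RNAi arrays. None of the 3 passed the test between groups (limma adjusted p of 0.847, 0.847 and 0.849). On the first principal component of the 6620 brighter probe sets, which held 38.2% of their variance, RNAi replicates 1 and 2 had 37.5 and 19.3. The other 5 arrays lay between -24.8 and -0.27.

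AS1, named for asparagine synthetase, ran against ASP1. It read 3.24, 6.07, 7.93 and 5.21 in the RNAi arrays and 6.30, 6.39 and 7.27 in the vector arrays. Across the 7 arrays Pearson's r was -0.90 (exact permutation p = 0.0218, adjusted over 10 pairs 0.218) and Spearman's rho was -0.68 (exact permutation p = 0.110, adjusted 0.548). A hypothesis that the genes are regulated against each other needs r below -0.5 without the 2 arrays farthest from the median of ASP1, RNAi replicates 1 and 4. Without them r was -0.0713 over 5 arrays (95% interval -0.90 to 0.87), so an r of -0.90 needs those 2 arrays, and the 5 others span too little of ASP1 to decide the hypothesis.

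The number of called probe sets was 0 in the real split of the 7 arrays into 4 and 3 and 0 in the highest other, and lists past the threshold were 0 in the real split and 4 in the highest other. A count of 0 is reached by all 35 of 35 splits by construction, so these counts say nothing for or against chance. The real split gave 3260 probe sets with unadjusted p under 0.05, and 5 of the 34 other splits gave as many, up to 4292. Non-overlapping groups among the brighter probe sets numbered 635 in the real split and up to 905 in another, which set RNAi replicates 1, 2 and 3 against RNAi replicate 4 with the vector arrays.

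Over all probe sets, 58.5% of those with unadjusted p under 0.05 were lower in RNAi nodules. The 3085 with 1 gene leaned the other way, with 109 higher and 80 lower (42.3%). Of the 33277 probe sets with the higher means, 63.6% of those with unadjusted p under 0.05 were lower in RNAi nodules. As strong a lean to 1 side arose in 5 of 35 splits, the real one included, up to 71.8%, so chance could not be excluded. A shift left by the normalization would bring the share to 55% or less. It was 59.3% after quantile normalization and 69.0% after median centring, which moves all probe sets of an array alike. Leaving out each array as well gave values down to 51.7% and 61.5%, so a shift stays open. A single array as the source would also bring the share to 55% or less once left out. The share was 56.5% without RNAi replicate 4 (95% interval 54.6% to 58.3%) and 58.3% without RNAi replicate 2. The interval spans 55%, so a single array as the source stays open. Probe sets are not independent, which makes the interval too narrow.

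UR2 was singled out for its small p among genes whose groups did not overlap. It did not pass the test (limma adjusted p = 0.847), so its lower value may be chance. Other candidates are less nodule tissue in the RNAi samples, the loss of GmbHLHm1, and 1 array. Less nodule tissue would lower the other nodulins too, and a median of -0.5 or below was set as the bound for this. The 13 nodulins other than the uricases had a median of 0.0515, with members from -0.64 to 0.56. This argues against a loss of that size in these samples. The 95% bootstrap interval of the median was -0.09 to 0.19. It was taken over genes, so it leaves out the spread between plants and treats the genes as independent. Over leaving out each array the UR2 difference ran from -1.20 to -0.80, the latter without vector replicate 1 (95% interval -1.43 to -0.18). Since UR2 was picked for groups that did not overlap, leaving out an array could not reverse its sign. The share of a single array cannot be told apart with 3 vector arrays. An effect of the hairpin stays open, since the target itself was not measured under its name.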
